A study of Mus musculus with 12 samples.

How the data were processed

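Total RNA of brown adipose tissue from 6 WT and 6 SIRT1tg mouse samples was labelled with biotin and hybridised to Illumina arrays, per the labels' protocols. The submitters' processing notes name GenomeStudio, Illumina's array software, and its version is not given in the sources used here. Deposited were non-normalised mean bead signals, which are intensity values on a linear scale per the file headers, each with a detection p-value that the deposited file gives per probe and array. The detection p takes about 798 steps between 0 and 1. A further deposited table of the series holds intensity values that the authors had processed. By their values they were on a linear scale, background-subtracted and not centred, since 26.1% lay at or below 0. They were also normalised between arrays, since the upper quartile was 57.7 in every column, but the values do not show by which method. The column medians of these processed values were 5.757, 5.743, 5.735, 5.752, 5.752 and 5.746 for WT replicates 1 to 6 and 5.738, 5.745, 5.733, 5.705, 5.759 and 5.732 for SIRT1tg replicates 1 to 6. The columns of the non-normalised table name the group and a number but not the replicate, so they were used as replicates of their group, and each array's best-correlated column of the processed table belonged to the same group.

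Signals were background-corrected and quantile-normalised with neqc of limma 3.58.1 in R 4.3.3, which fits a normal-exponential model through the detection p-values and adds an offset of 16, and were analysed on the log2 scale. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation and were used, and 1719 did not. Through the gene identifiers, 23962 were matched to the RefSeq gene table, which left 0 symbols changed, and its gene positions were used only to find the neighbours of Sfxn1, since the files name no genome build. Probes with a detection p under 0.05 on at least 6 of 12 arrays were kept (11413, of which 10771 were named), and each gene was represented by the probe with the highest mean signal, chosen without regard to group. This gave 8035 genes, 2028 of which had more than 1 detected probe. Log2 fold changes are SIRT1tg minus WT, and a fold is 2 to that power; folds of dim genes are compressed by the background and the offset.

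Groups were compared with lmFit and eBayes of limma, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Every adjusted p of a single gene is from this fit unless said otherwise. Gene lists (47 fixed, 45 with at least 5 measured genes) were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. The signal of a list on an array is the mean over its genes of the log2 signal centred over the 12 arrays, and its difference between groups has a 95% interval from a linear model and an exact two-sided permutation p. Members that "rose" or "fell" passed the test named beside them. The code was tested on simulated data made from these 8035 genes with 200 changed. At a log2 change of 0.5 they recovered 53.6% and at 1 they recovered 90.6% of the changed genes, 5.4% of the calls were false, and lists shifted by 0.3 were recovered in 96% of cases. Genes were simulated independently and without the number range of the arrays. These rates, above all that of the lists, need not hold for correlated genes.

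The rule for named genes was fixed before the data were examined. It took Sirt1, 11 anchor genes of brown fat, up to 10 genes per direction among those past the threshold, up to 4 members with the smallest p in the direction of each biological list past the threshold and the 2 brightest members of each list of another cell type or sample check. Other genes that are named, including members that passed over their list alone, were chosen after their values were seen. The alternatives were another background correction (normexp with an offset of 50) or none, median scaling or cyclic loess, the processed values, other filters, the mean of a gene's probes, every probe alone, array weights, a robust trended prior and leaving out each array. Added after the data were examined were the number range of the column names as a block, each range alone, the muscle signal as a covariate, leaving out the 5 arrays above the mean muscle signal, and the replicate number as a block on the processed values. The markers of other cell types were compared in 3 forms, all chosen after the data were examined, namely macrophage against endothelial markers, the largest contrast of any pair of 8 marker lists, and matrix or macrophage against endothelial markers with the p taken over all 28 pairs. Those 8 lists leave out skeletal muscle. The chip that carried each array is not given in the sources used here, so no chip block was run.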

Results

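Brown adipose tissue of mice aged 3 months, on a C57Bl/6N background per the labels, was profiled on Illumina expression arrays. The samples fell into 2 groups of 6, wild type (WT) and mice carrying a SIRT1 transgene on both chromosomes (SIRT1tg). SIRT1 is a protein deacetylase that uses NAD+, and the comparison asks which transcripts of brown fat differ when it is overexpressed. Each array carried 25697 probes, of which between 11221 and 12108 (43.7% to 47.1%) were detected above the negative control beads. Median signals before normalisation lay between 98.95 and 108.6. After filtering, 8035 genes were tested, and across them the normalised signals of pairs of arrays correlated at r = 0.959 to 0.9897. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples, and the number of arrays limits the precision. The column names carry a number whose meaning the labels do not give, and these numbers form a low and a high range, each with 3 arrays of each group. In the order of that number the arrays are called WT 1 to 6 and SIRT1tg 1 to 6, with 1 to 3 in the low range, an order unrelated to the replicate numbers of the labels.

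In SIRT1tg brown fat 9 genes rose and 3 fell against WT. Sirt1 rose 2.59-fold, from a normalised log2 signal of 6.88 ± 0.32 (SD, n = 6) to 8.26 ± 0.21 (SD, n = 6). The largest change was that of Sfxn1, a mitochondrial serine transporter, which fell 7.25-fold, from 11.43 ± 0.27 to 8.57 ± 0.37 (SD, n = 6 each). Dlk1, a membrane protein of preadipocytes that restrains adipocyte differentiation, rose 2.31-fold, and Nampt, the rate-limiting enzyme of NAD+ salvage, rose 1.73-fold.

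These 12 of 8035 genes passed limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05. The log2 fold change of Sirt1 was 1.37 ± 0.14 (SE), with an adjusted p of 0.00049, and an exact two-sided permutation test of its 6 against 6 signals gave p = 0.00216, the smallest value that the 924 splits can give. A single Sirt1 probe was measured, and the labels do not say whether the transgene carries the part of the transcript that it reads. The log2 fold change of Sfxn1 was -2.86 ± 0.17 (SE; adjusted p = 3.85e-07), and a further Sfxn1 probe gave -2.66 ± 0.18. Dlk1 had a log2 fold change of 1.21 ± 0.15 (adjusted p = 0.00333). For Nampt it was 0.79 ± 0.14 (adjusted p = 0.0431), and 0.62 at its other detected probe.

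The remaining genes that rose did so by 1.43-fold to 1.71-fold. They were L3hypdh, an enzyme of hydroxyproline breakdown (log2 fold change 0.77 ± 0.13), Timp4, an inhibitor of matrix metalloproteinases (0.77 ± 0.11), Ankrd10 (0.76 ± 0.12), Insig1, an endoplasmic reticulum protein that holds back SREBP processing (0.69 ± 0.12), Kazald1, a secreted protein (0.63 ± 0.11), and Slc4a8, a sodium-dependent bicarbonate transporter (0.52 ± 0.09). The remaining genes that fell were Zfp763, which encodes a zinc finger protein (-0.67 ± 0.12), and Rbm43, which encodes a protein with an RNA-binding motif (-0.48 ± 0.08). The adjusted p of these 8 genes lay between 0.0166 (Timp4) and 0.0459 (Zfp763). Kazald1 was detected on 2 of 6 WT arrays and on 6 of 6 SIRT1tg arrays. The other detected probes of Insig1 did not move with the one tested, at -0.04 and -0.16. Each of the 12 genes separated the groups without overlap, as did 106 genes in all, where chance gives 17.4 (0.216% of those tested). At an unadjusted p under 0.05, 1225 genes differed, where chance gives 402. Both chance values are averages, and correlation between genes makes such counts vary widely around them. How far these counts vary between regroupings of the arrays was not tested.

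**Figure D1:**
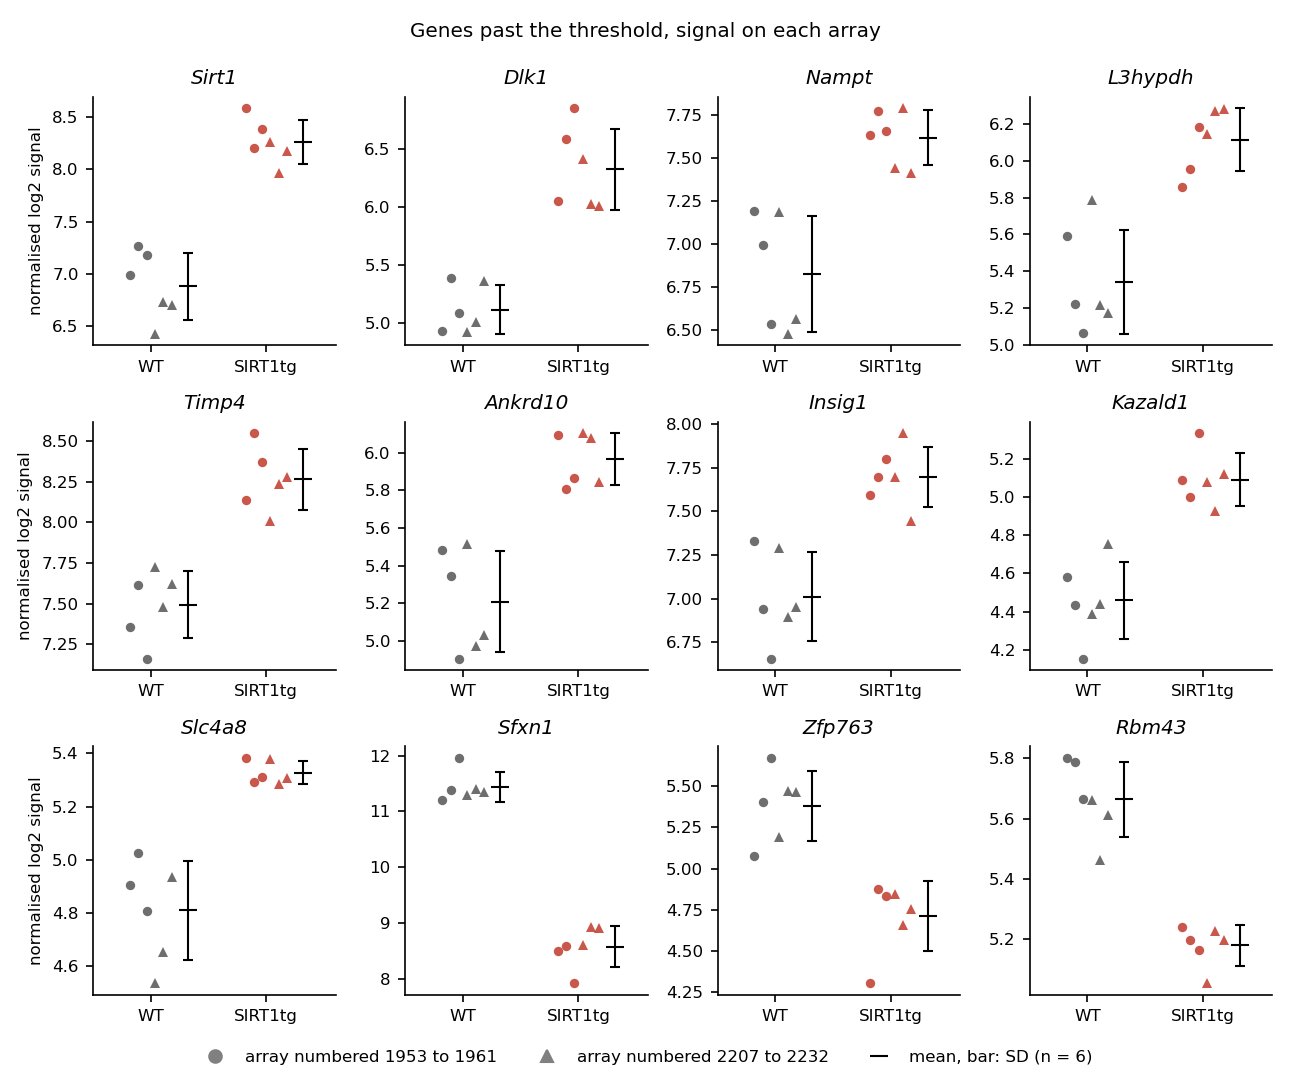
Normalised log2 signal (vertical axis, own scale in each panel) of the 12 genes past the threshold on each WT and SIRT1tg array, with circles for the low and triangles for the high number range and bars for mean ± SD (n = 6). In every panel the groups do not overlap, and Sfxn1 shows the widest gap, with SIRT1tg arrays between 7.92 and 8.93 and WT arrays between 11.20 and 11.96.

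With the number range as a block, an alternative chosen after the data were examined, 84 genes passed (54 higher and 30 lower in SIRT1tg). They included all 12 above. Sirt1 was higher by 1.24 in the low and by 1.51 in the high range on the log2 scale, Dlk1 by 1.36 and 1.05, Nampt by 0.78 and 0.81, and Sfxn1 was lower, at -3.18 and -2.54. The range itself separated 404 genes, 194 of them higher and 210 lower on the high-numbered arrays. Each range alone holds 3 arrays against 3 and gave 1 gene (low) and 4 genes (high). The count of 12 rests on single arrays: leaving out a single array gave between 3 genes (without SIRT1tg 2, 3, 5 or 6) and 151 (without WT 1). Sirt1, Sfxn1 and Dlk1 passed whichever array was left out.

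**Figure D2:**
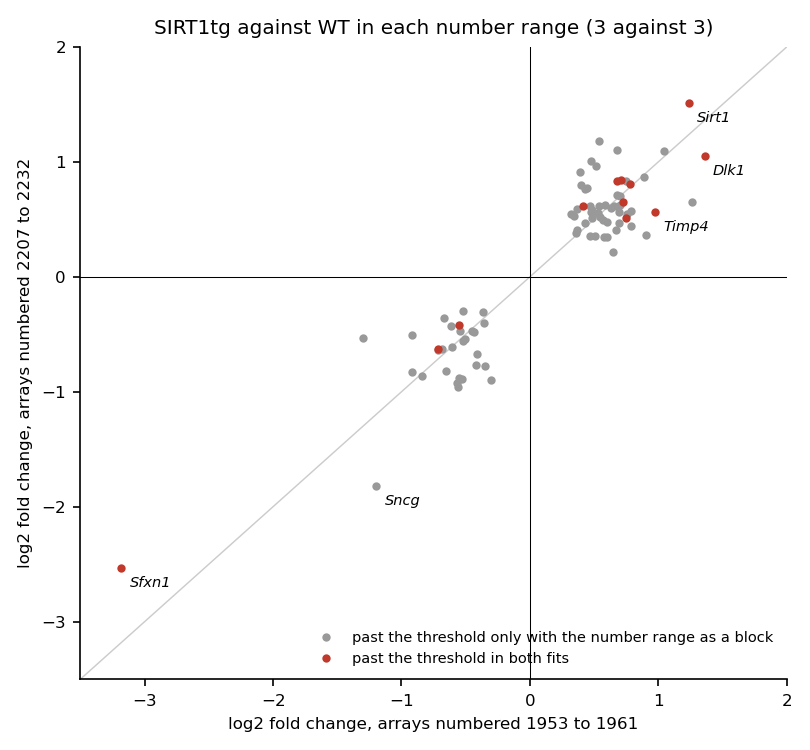
Log2 fold change of SIRT1tg against WT for the 84 genes past the threshold with the number range as a block, in the low-numbered arrays (horizontal axis) and the high-numbered arrays (vertical axis), 3 against 3 in each. Red points are the 12 genes that also pass without the block, the grey line marks equal change, and choosing genes by the blocked test itself favours the same side of 0 in both ranges.

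The anchor genes of brown fat, fixed before the data were examined, did not pass. Ucp1, the uncoupling protein that makes heat, stood at 13.52 ± 0.15 in SIRT1tg and 13.40 ± 0.40 in WT (SD, n = 6 each), a log2 fold change of 0.12 with a 95% interval of -0.22 to 0.46. Ppargc1a, a coactivator of mitochondrial biogenesis, had a log2 fold change of 0.96 (0.15 to 1.77; adjusted p = 0.235). SIRT1tg 1 read 11.14 for Ppargc1a and the other SIRT1tg arrays 8.36 to 9.56, and leaving out 1 array brought the difference down to 0.59. The intervals were narrow around 0 for Cidea, a lipid droplet protein (0.01, from -0.15 to 0.16), Lpl, lipoprotein lipase (-0.04, from -0.24 to 0.16), Pparg, the master regulator of adipocytes (0.06, from -0.19 to 0.31), and Adipoq, adiponectin (0.03, from -0.25 to 0.31). The other detected probes of Pparg, which were dimmer, stood at 0.46 and 0.22. Ucp1, Cidea and Lpl lie near the top of the signal range, where quantile normalisation gives arrays shared values, so their intervals come from a compressed measure. They were wider for the glucose transporter Slc2a4 (0.20, from -0.19 to 0.59) and the fatty acid elongase Elovl3 (0.08, from -0.86 to 1.01). The probe of Dio2 was detected on 2 of 12 arrays and that of Prdm16 on 0 of 12, so neither was tested, and Adrb3 was not analysed here.

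Of 45 gene lists fixed before the data were examined, 5 shifted up and 5 shifted down in SIRT1tg (camera with a preset correlation of 0.01, adjusted p under 0.05). None of the 10 calls holds with a correlation estimated for each list, where the lowest adjusted p was 0.252 and 5 lists had an unadjusted p under 0.05. Fry called 5 lists, 4 of them among the 10 and the sirtuin list. An exact permutation test of the mean signal of each list, adjusted over the 45 lists, passed 6, namely the interferon, cell proliferation, adrenergic, sirtuin, hypoxia and matrix lists. The sirtuin list holds the overexpressed gene Sirt1 (1.37) and Nampt (0.79), and the other 12 members had a mean of 0.02 against 0.17 for all 14, so both of its passes rest largely on genes already named above.

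Genes of fibroblasts and the extracellular matrix were lower in SIRT1tg as a list, as were interferon-stimulated genes and macrophage markers. The matrix list shifted down with a median log2 fold change of -0.45 over 23 measured genes, 20 of them lower (camera adjusted p = 2.95e-08; adjusted p = 0.278 with an estimated correlation). Over all genes tested 0 members fell, and adjusted over the list alone 12 did, among them Lum (-1.07), Pdgfra (-0.64), Col6a1 (-0.53) and Sparc (-0.31). Dcn, a matrix proteoglycan and the other abundant member, also fell over the list alone (-0.37, against -0.15 at its other detected probe). All 20 measured interferon-stimulated genes were lower, with a median of -0.33 (camera adjusted p = 2.95e-08; adjusted p = 0.252 with an estimated correlation). Of these 7 fell when adjusted over the list alone, among them Ifit3 (-0.74), Usp18 (-0.54), Oasl2 (-0.54) and Tap1 (-0.38), and over all genes tested 0 did. Ifit3 and Usp18 passed over all genes with the number range as a block (adjusted p = 0.0432 for both).

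The macrophage list shifted down with a median of -0.43, with 18 of 21 measured genes lower (camera adjusted p = 1.78e-06; adjusted p = 0.582 with an estimated correlation). Lyz2 (-0.96), C1qb (-0.85) and the antigen presentation genes Cd74 (-0.43) and H2-Ab1 (-0.43) were among the 9 that fell adjusted over the list alone, against 0 over all genes tested. The shift rests on WT 3 and WT 4, at 0.84 and 0.66, while the other WT arrays (-0.23 to 0.06) lie within the SIRT1tg arrays (-0.45 to 0.23). The proliferation list shifted down with a median of -0.21 over 11 genes, 10 of them lower (camera adjusted p = 0.0165, and 0.252 with an estimated correlation). This list lost its call in 3 of 18 settings besides leaving out an array, the estimated correlation among them, with medians from -0.39 to -0.06. Its members did not pass singly; the replication and cell cycle genes Mcm4 (-0.36), Cdk1 (-0.35), Rrm1 (-0.35) and Mcm5 (-0.33) had the smallest p. Cdk1 was detected on 5 of 6 WT arrays and 1 of 6 SIRT1tg arrays, so its difference is set against background. The medians of these lists were below 0 in both number ranges, at -0.44 and -0.42 for matrix, -0.30 and -0.39 for interferon, -0.37 and -0.50 for macrophages, and -0.22 and -0.12 for proliferation (low and high). Choosing lists called on these same arrays itself favours the same sign in both ranges. The proliferation list passed in the low range alone (camera adjusted p = 0.0219) but not in the high range alone (0.138).

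Skeletal muscle transcripts differed strongly between arrays. The muscle list shifted down with a median of -1.14 over 21 genes, all lower in SIRT1tg (camera adjusted p = 0.00268, and 0.659 with an estimated correlation), and 0 members fell. This list lost its call in 6 of 18 settings besides leaving out an array and reversed in 1, with medians from -1.97 to 0.18. Its mean signal was above the average of the 12 arrays on 4 of 6 WT arrays and on 1 of 6 SIRT1tg arrays, and the group difference of -1.13 had a 95% interval of -3.35 to 1.10. The calcium pump Atp2a1 read 8.65 ± 3.27 in WT and 6.49 ± 2.99 in SIRT1tg (SD, n = 6 each). Myl1, the brightest member, read 11.85 ± 0.52 and 11.62 ± 0.51, a difference of -0.24, against 0.20 at its other detected probe. The matrix, interferon and macrophage lists taken as 64 genes were lower in SIRT1tg by a mean of -0.39, and by -0.40 with the muscle signal of each array as a covariate. WT 3 (0.56) and WT 4 (0.50) read highest, while WT 1 (-0.06) and WT 6 (-0.07) lay within the SIRT1tg arrays (-0.32 to 0.01). Leaving out WT 3 gave -0.32 and leaving out WT 4 gave -0.33.

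**Figure D3:**
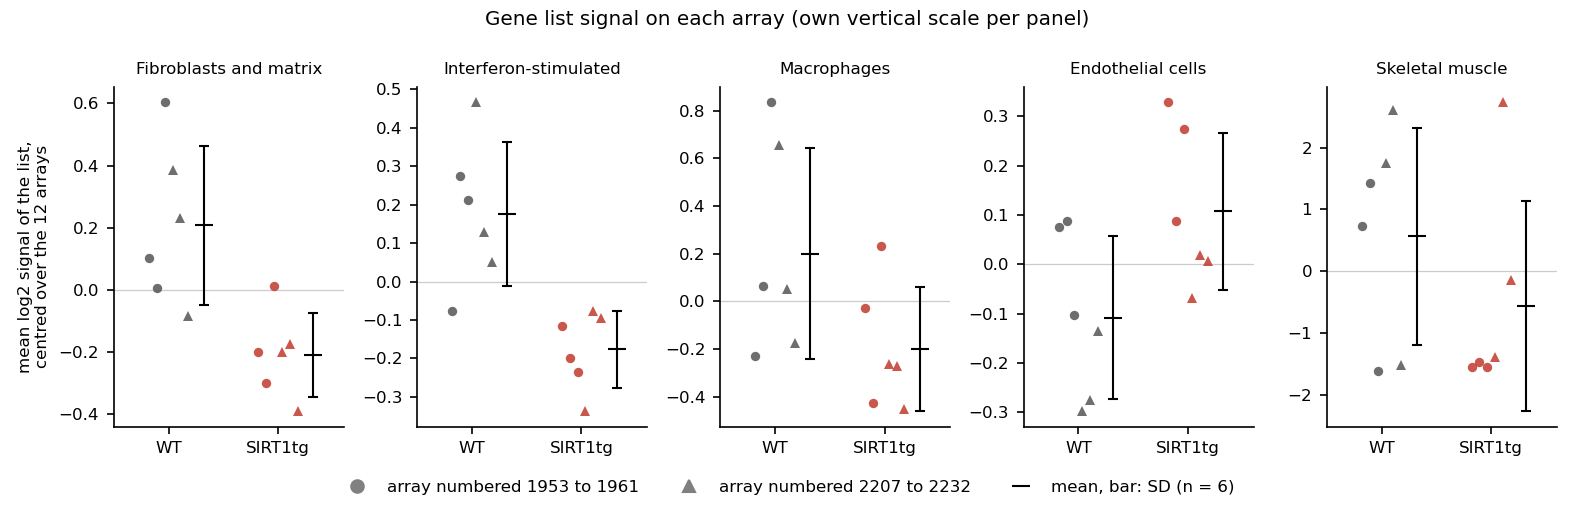
Mean log2 signal of 5 gene lists on each WT and SIRT1tg array (vertical axis, each gene centred over the 12 arrays, own scale in each panel), with circles for the low and triangles for the high number range and bars for mean ± SD (n = 6). The muscle panel runs from -1.62 to 2.74 and spans both groups. The group means of the matrix list are 0.21 in WT and -0.21 in SIRT1tg, and the groups overlap. WT 2 (0.007) and WT 6 (-0.084) lie within the SIRT1tg arrays (-0.390 to 0.012).

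Endothelial markers moved the other way. The endothelial list shifted up with a median of 0.18 over 19 genes, 15 of them higher in SIRT1tg (camera adjusted p = 0.000223; adjusted p = 0.582 with an estimated correlation). The vascular transcription factors Sox18 (0.63) and Sox17 (0.61) and the receptor phosphatase Ptprb (0.51) were the 3 that rose adjusted over the list alone, against 0 over all genes tested. Sox18 and Sox17 passed over all genes with the number range as a block (adjusted p = 0.0462 and 0.0380). The brightest members were Egfl7 at -0.04 and the water channel Aqp1 at 0.31, neither of which passed, and each had another detected probe of the opposite sign (0.12 for Egfl7 and -0.01 for Aqp1). Heat shock genes shifted up with a median of 0.24, 16 of 18 being higher (camera adjusted p = 0.000947; adjusted p = 0.434 with an estimated correlation). None passed singly; the chaperone genes Hspa8 (0.47), Hspb8 (0.49), Hspe1 (0.49) and Chordc1 (0.22) had the smallest p.

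The adrenergic and cyclic AMP list shifted up with a median of 0.20, 12 of 13 genes being higher (camera adjusted p = 0.00329; adjusted p = 0.252 with an estimated correlation). Prkar2b, a regulatory subunit of protein kinase A (0.60), was the 1 member that rose adjusted over the list alone, against 0 over all genes tested. The adenylyl cyclase Adcy4 stood at 0.42, the phosphodiesterase Pde4d at 0.45 and the transcription factor Crem at 0.39. Leaving out 1 array brought Crem down to 0.21 and Pde4d to 0.23, and the other detected probes of Crem stood at 0.08 and 0.10. Genes of branched-chain amino acid breakdown shifted up with a median of 0.08, 14 of 20 being higher (camera adjusted p = 0.0335, and 0.425 with an estimated correlation). Their mean difference was 0.18 (95% interval 0.06 to 0.31), with an exact permutation p of 0.0835 adjusted over the lists. Leaving out 1 array ended the camera call of this list in 4 of 12 cases (adjusted p up to 0.0835) and moved the median between 0.04 and 0.14. Median scaling brought the median to 0.00, where the median over all genes was -0.10. Of 18 settings besides leaving out an array 7 ended the call. Adjusted over the list alone 2 rose, Mccc1, a subunit of methylcrotonoyl-CoA carboxylase (0.86), and Acadsb, an acyl-CoA dehydrogenase (0.65), and over all genes tested 0 did, though Mccc1 passed with the number range as a block (adjusted p = 0.0432). Aldh6a1 and Hsd17b10 stood at 0.47 each. Subunits of respiratory complex I shifted up with a median of 0.04, 23 of 32 being higher (camera adjusted p = 0.0335, and 0.659 with an estimated correlation). Their mean difference was 0.13 (95% interval 0.02 to 0.23), with an exact permutation p of 0.134 adjusted over the lists. Of these 18 settings 7 ended the call, such as the number range as a block (adjusted p = 0.0536) and median scaling, which turned the median to -0.03. Leaving out 1 array ended it in 5 of 12 cases (adjusted p up to 0.119). Over all genes tested 0 rose and, adjusted over the list alone, 3 did, namely Ndufb2 (0.73), Ndufb9 (0.70) and Ndufb5 (0.52), while Ndufb10 stood at 0.53 (0.34 with 1 array left out).

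**Figure D4:**
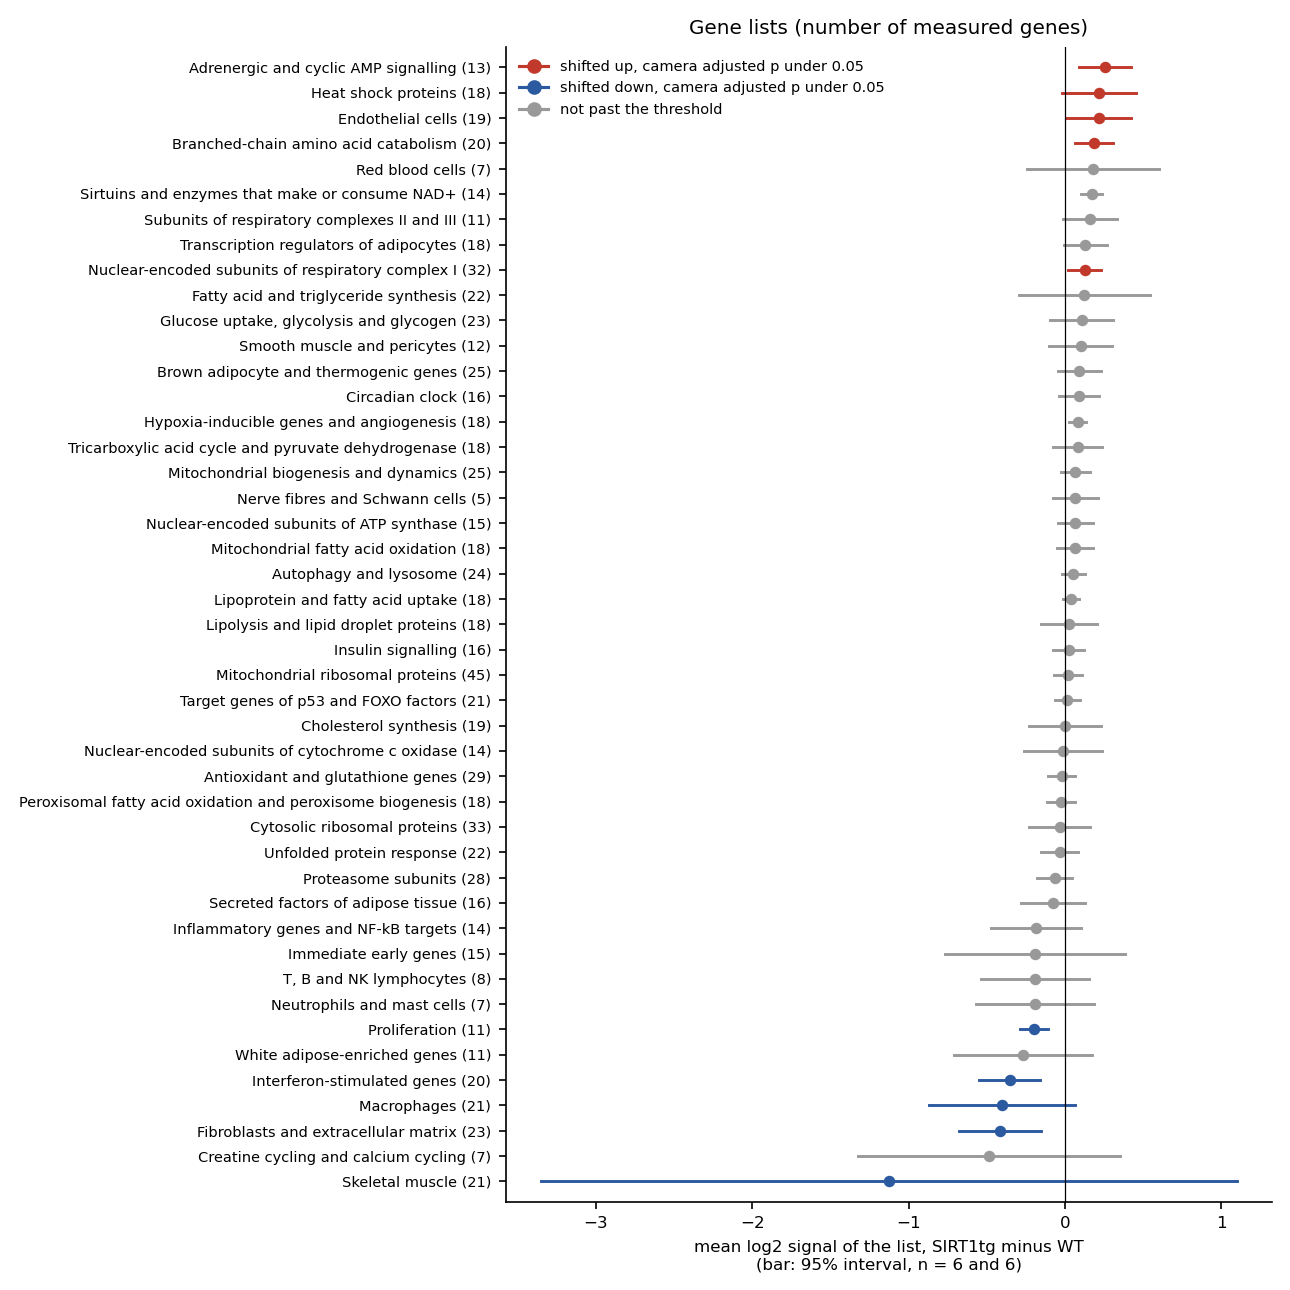
Difference of the mean log2 signal of each of the 45 gene lists between SIRT1tg and WT (horizontal axis, points with 95% intervals, n = 6 and 6), with the number of measured genes in brackets. Red and blue mark the lists past camera's threshold, and the muscle list at the bottom has the widest interval, from -3.35 to 1.10.

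The other 35 lists did not pass, with adjusted p between 0.0578 and 0.957. Closest was the list of sirtuins and NAD+ enzymes (median 0.10, adjusted p = 0.0578), whose 2 members past the threshold were Sirt1 and Nampt. Thermogenic genes had a median of 0.07 over 25 genes, 17 of them higher (adjusted p = 0.289). Mitochondrial lists had medians close to 0: complexes II and III 0.03 (0.184), cytochrome c oxidase 0.03 (0.356), ATP synthase 0.04 (0.356), the tricarboxylic acid cycle 0.04 (0.374), fatty acid oxidation 0.02 (0.288), biogenesis 0.01 (0.441) and mitochondrial ribosomes -0.03 (0.877), with the adjusted p in brackets. The mean difference was larger for complexes II and III, at 0.16 (95% interval -0.01 to 0.33), and 0.08 for the tricarboxylic acid cycle. Close to 0 were also the medians of peroxisomal oxidation at -0.03 (0.735), lipolysis at 0.00 (0.697), fatty acid uptake at 0.03 (0.541), glucose use at 0.01 (0.269), insulin signalling at 0.02 (0.957), adipocyte transcription regulators at 0.05 (0.0872) and cholesterol synthesis at -0.04 (0.697). Fatty acid synthesis stood at 0.11 (0.168), creatine and calcium cycling at -0.20 (0.293), white adipose genes at -0.12 (0.674) and secreted adipose factors at -0.08 (0.877). Several of these lists followed the muscle list over the 12 arrays, namely creatine and calcium cycling (r = 0.98), cytochrome c oxidase (r = 0.90), white adipose genes (r = 0.79) and secreted adipose factors (r = 0.70), while thermogenic genes (r = -0.63) and biogenesis (r = -0.60) ran against it. Among stress and turnover lists the medians were -0.15 for inflammatory genes (0.168), -0.06 for the unfolded protein response (0.697), -0.08 for antioxidant genes (0.674), -0.08 for p53 and FOXO targets (0.697), 0.04 for autophagy (0.441), 0.03 for hypoxia (0.405), -0.04 for cytosolic ribosomes (0.450) and -0.07 for the proteasome (0.0872). Apart from the 12 genes above, single members passed when adjusted over their list alone and, without a block, not over all genes. Those that rose were Ppp1r3c (1.07) and Hk2 (0.66) of glucose use, Sdhd (0.79) of complex II, Atp5e (0.79) of ATP synthase, Cebpb (0.55) of the adipocyte regulators, Ptpn1 (0.55) of insulin signalling, Egln3 (0.69) of hypoxia, and Cdkn1a (1.08) and Pck1 (0.83) of the p53 and FOXO targets. Those that fell were Sncg (-1.51) of the white adipose genes, Ccl4 (-0.71) of the inflammatory genes, Pltp (-0.51) of the secreted factors and Psmc3 (-0.32) of the proteasome. Ppp1r3c (adjusted p = 0.0439) and Sncg (adjusted p = 0.0470) passed over all genes with the number range as a block. The mean difference was 0.11 for glucose use and 0.13 for the adipocyte regulators. The median, the mean and the direction of the test differed in sign for 4 lists, cytochrome c oxidase, mitochondrial ribosomes, p53 and FOXO targets and cholesterol synthesis.

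Circadian clock genes went both ways, and the list did not shift (median 0.11 over 16 genes, adjusted p = 0.236). Adjusted over the list alone 3 rose, the period genes Per2 (1.05) and Per1 (0.76) and the deubiquitinase gene Usp2 (0.71), and 2 fell, the transcription factor genes Dbp (-1.24) and Nr1d1 (-1.07). Over all genes tested 0 of them passed, with adjusted p between 0.106 and 0.161.

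Markers of further cell types did not pass as lists, nor singly over all genes without a block, and leaving out 1 array moved several of the values below by more than 1.5 times, such as Cd8b1 to -0.25, Nkg7 to -0.16, S100a8 to -0.24 and Hdc to 0.04. Lymphocyte markers had a median of -0.17 (adjusted p = 0.164; Nkg7 -0.26, Cd8b1 -0.41), neutrophil and mast cell markers -0.16 (0.405; Hdc 0.20, S100a8 -0.43), red cell markers 0.13 (0.288; Hba-a1 0.12, Hbb-bt 0.61), nerve markers 0.07 (0.731; Pmp22 0.21, Mbp 0.07, with -0.58 at another detected probe of Mbp) and smooth muscle markers 0.11 (0.202; Acta2 0.14, Tpm1 0.00). The exception over the list alone was the B cell gene Cd79b, which fell (-0.52), and which passed over all genes with the number range as a block (adjusted p = 0.0432). The globin probes can share signal between near-identical globin genes. Immediate early genes had a median of -0.24 (0.356; Dusp1 -0.01, Egr1 -0.84), with wide spreads, Egr1 having an SD of 1.28 in WT and 1.03 in SIRT1tg, and Junb (-0.71) passed with that block (adjusted p = 0.0432). Skin and sex chromosome lists had 3 measured genes each and were not tested, and their brightest genes stood at -0.10 (Krt10), 0.17 (Lor), 0.31 (Eif2s3y) and 0.14 (Kdm5d).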

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

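A test for a value apart from the rest of its group (Dixon) was made in 158 groups of 6 values, the named genes, the lists past the threshold and the number of detected probes. It marked 8 values, where chance alone gives 7.9. Elovl3 read 8.46 on SIRT1tg 3, with the other SIRT1tg arrays between 6.21 and 6.67. Sfxn1 read 11.96 on WT 3, with the other WT arrays between 11.20 and 11.40. On SIRT1tg 1, Crem read 6.30 (others 4.99 to 5.36), Pde4d 9.40 (others 7.85 to 8.39), Rrm1 5.54 (others 6.12 to 6.27) and the adrenergic and cyclic AMP list 0.42 (others 0.01 to 0.14). Rrm1 also read 6.81 on WT 6 (others 6.25 to 6.41). The muscle list read 2.74 on SIRT1tg 5, with the other SIRT1tg arrays between -1.56 and -0.15.

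Slc4a1, the band 3 anion exchanger of red cells, was the only gene whose difference between the groups itself differed between the number ranges (limma, adjusted p = 0.0264), by 1.90, being -0.79 in the low and 1.11 in the high range. Among 642 detected probes without a gene symbol, which were not part of the comparison, 2 differed between the groups when tested on their own, ILMN_1233905 by 0.84 (adjusted p = 0.0286) and ILMN_2974720 by -0.67 (adjusted p = 0.0275).

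Both tests of the muscle signal below were chosen after the signal had been seen. Skeletal muscle carried over in some dissections could produce the spread of the muscle list, but its genes moving together within a group (mean pairwise correlation 0.9016) restates that spread and does not test its origin. Of the 21 measured muscle genes, 1 stands in another list and 4 were detected on all 12 arrays; Myl1 stayed between 10.96 and 12.47 on every array, while Acta1 ranged from 4.32 to 11.79 and Pvalb from 4.32 to 11.12. A difference between the genotypes cannot give the spread within a group, from -1.62 to 2.61 in WT and from -1.56 to 2.74 in SIRT1tg. For the group means, such a difference cannot be told apart from uneven dissection, since the exact two-sided permutation test gave p = 0.303. Muscle tissue weighed or stained in the same depots would separate these.

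For Sfxn1, the test of its other probe was chosen after the result had been seen and that of its neighbours before. A fault or a sequence difference at a single probe could give a false drop. One confined to the tested probe would leave the other probe unchanged, and that probe stood at -2.6637. The positions of the probes were not compared, so a sequence difference that lies under both is not excluded. Lower expression of the wider chromosomal region could pull Sfxn1 down, but the 10 nearest measured genes had a median of -0.0776, from -0.40 (Fbxw17) to 0.61 (4833439L19Rik), and none passed without the number range as a block. With that block 4833439L19Rik was higher (adjusted p = 0.0432). The nearest measured gene on each side, Sptlc1 (-0.28, adjusted p = 0.303) and Thoc3 (-0.26, adjusted p = 0.208), was lower without passing. Neither test separates a transcriptional response to SIRT1 from a lesion confined to Sfxn1, for example at an insertion of the transgene, and mapping the insertion site would.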

How the results depend on the processing

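Under settings other than leaving out an array, 1015 of 1131 values of the 67 named genes besides Sirt1 kept their sign and their side of the threshold. Of the others 69 were weaker (no longer past it), 12 stronger (newly past it) and 35 reversed. For the 10 lists 146 of 180 kept direction and call, with 33 weaker and 1 reversed. The size of a value does not enter, and Hspe1 ran from 0.02 to 0.96 while counting as kept in all 17 settings. Under leave-one-out 692 of 804 gene values and 109 of 120 list values kept sign and call, again whatever their size. The reversals concern genes that did not pass, whose values lie near 0 or spread widely, apart from the muscle list. The median of complex I also changed sign with median scaling (-0.03, where the median over all genes was -0.10), while its test kept the upward direction without passing. For the counts that moved, the cause was not tested. Of 100 regroupings of the 12 arrays into 6 against 6 (462 exist), the real one included, 1 gave at least 12 genes, the real one, and the highest other count was 1. For lists, 23 of 100 gave at least 10, and the highest other count was 19, so the number of lists is not beyond chance. With the number range as a block 1 of 100 gave at least 84 genes, and the highest other count was 24.

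Gene counts by setting were 3 with median scaling, 5 with the processed values (3 higher, 2 lower), 26 with detection on all 12 arrays (10 shared with the 12), 163 with array weights and 24 with a robust trended prior. The counts were closer to 12, though not always of the same genes, with another background correction (13, of which 8 are among the 12), none (13, 8 shared), cyclic loess (13, 12 shared), no filter (15, 9 shared), a stricter detection p (12, all shared), the mean of the probes of a gene (14, 11 shared) and every detected probe on its own (18). With settings chosen after the data were examined they were 84 with the number range as a block, 1 and 4 in the low and high range alone (1 and 2 shared), 29 with the muscle signal as a covariate (11 shared) and 1 without the muscle-rich arrays. Leave-one-out gave 3 genes without SIRT1tg 2, 3, 5 or 6, 4 without SIRT1tg 4 or WT 3, 5 without WT 5, 6 without WT 2, 8 without WT 6 (5 shared), 13 without SIRT1tg 1 (8 shared), 36 without WT 4 and 151 without WT 1. List counts were 16 with array weights, 0 with an estimated correlation and 5 with fry.

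The replicate numbers of the labels are shared by the groups, and a block on them was run on the processed values alone, where columns carry them. Same-number correlations ran from -0.12 to 0.39, against a mean of -0.02 for other numbers, and 5 of 12 samples correlated best with their own number. A pairing is thus neither shown nor excluded. With this block 1 gene passed, and Sirt1 was 1.48 (adjusted p = 0.0560).

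Sirt1 was 1.24 in the low range alone (adjusted p = 0.0869) and 1.38 without the muscle-rich arrays (adjusted p = 0.0520), and from 0.94 to 1.51 over all settings, passing in 14 of the 17 besides leaving out an array. Over these 17 settings Sfxn1 ran from -3.18 to -2.54 and passed in 17. Dlk1 ran from 0.47 to 1.72 and passed in 13, and Nampt ran from 0.50 to 1.03 and passed in 10.

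Values of opposite sign were, with median scaling, Cidea -0.05, Elovl3 -0.02, Pparg -0.06, Adipoq -0.06, Mbp -0.03 and Tpm1 -0.11, where the median over all genes was -0.10. With cyclic loess they were Dusp1 0.00, with the mean of probes Egfl7 0.04 and Mbp -0.13, and with array weights Elovl3 -0.05, Pparg -0.01, Adipoq -0.01 and Mbp -0.03. In the low range alone they were Ucp1 -0.16, Cidea -0.06, Adipoq -0.19, Hbb-bt -0.03, Krt10 0.05 and Kdm5d -0.30, and in the high range alone Egfl7 0.06, Mbp -0.12, Tpm1 -0.17 and Dusp1 0.40. With the muscle covariate they were Cidea 0.00, Elovl3 -0.20, Pparg 0.00, Myl1 0.06 and Mbp -0.06. Without the muscle-rich arrays they were Cidea -0.04, Elovl3 -0.69, Pparg -0.01, Myl1 0.17, Atp2a1 0.98, Pmp22 -0.01, Dusp1 0.25 and the muscle list 0.18. Since those arrays were removed by their muscle signal, this setting decides nothing about the muscle list and its genes.

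Leave-one-out ranges that crossed or touched 0 were Ucp1 0.00 to 0.20, Cidea -0.01 to 0.02, Lpl -0.09 to 0.00, Elovl3 -0.28 to 0.43, Pparg -0.01 to 0.11, Adipoq -0.06 to 0.10, Hba-a1 -0.05 to 0.31, Egfl7 -0.12 to 0.03, Mbp -0.05 to 0.15, Tpm1 -0.07 to 0.08, Krt10 -0.19 to 0.01 and Dusp1 -0.21 to 0.20. Leaving out an array moved over 1.5 times, without a change of sign, Ppargc1a (0.59 to 1.15), Slc2a4 (0.08 to 0.35), Ndufb10 (0.34 to 0.64), Crem (0.21 to 0.47), Pde4d (0.23 to 0.54), Myl1 (-0.42 to -0.13), Nkg7 (-0.43 to -0.16), Cd8b1 (-0.54 to -0.25), Hdc (0.04 to 0.30), S100a8 (-0.64 to -0.24), Pmp22 (0.11 to 0.36), Acta2 (0.06 to 0.25), Lor (0.08 to 0.24), Kdm5d (0.04 to 0.23) and Egr1 (-1.18 to -0.53).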

Other observations

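With the number range of the arrays as a block, a setting chosen after the data were examined, 72 further genes passed. Among those higher in SIRT1tg were Sox17 (0.61) and Sox18 (0.63), the only 2 of the 19 endothelial list members that passed. The transcription factor gene Gata2 (0.58), which stands in none of the lists, was also higher. So were Lamb1, a laminin of basement membranes (0.70), Ppp1r3c, which targets phosphatase 1 to glycogen (1.07), and the kinase gene Sgk1 (0.88). Among those lower were the lysosomal tetraspanin Cd63 (-0.85), the secreted glycoprotein Lgals3bp (-0.87), the Fc receptor Fcgr4 (-0.76), Serpinf1, which encodes an antiangiogenic serpin (-0.74), the cytokine signalling inhibitor Socs3 (-0.38) and Sncg, a synuclein of white adipocytes (-1.51). Their adjusted p lay between 0.0342 (Gata2) and 0.0495 (Lamb1 and Fcgr4).

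The number range separated more genes than the genotype did. Acly (1.97) and Acss2 (1.55), which make acetyl-CoA in the cytosol, Slc25a1 (1.46), the mitochondrial citrate carrier, and Fasn (1.45), fatty acid synthase, were higher on the high-numbered arrays, and Nnmt (-1.84) and the immediate early genes Fos (-1.80), Egr1 (-1.71) and Dusp1 (-1.20) were lower. Fn3krp, a kinase of glycated proteins, was detected on 6 of 6 WT and 0 of 6 SIRT1tg arrays, with a log2 fold change of -0.45 (adjusted p = 0.0543, and 0.0432 with the block). All 3 probes of Nnt, the mitochondrial transhydrogenase, were detected on 0 of 12 arrays. Nnt is known to be intact in C57BL/6N and disrupted in C57BL/6J mice, so this value is at odds with the background that the labels give, and the probes were not checked on other tissue. Xist was detected on 0 of 12 and the Y-linked Eif2s3y on 12 of 12.

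For the lower matrix, interferon and macrophage lists, the tests of muscle and of the number range were written before their values were known, and the 3 forms of the test between marker lists were chosen after the lists had been seen (macrophage against endothelial markers, exact p = 0.0173; the largest contrast of any pair, matrix against nerve markers, exact p = 0.00433; and the form below). Together their 64 genes differed by -0.39, a value without a p since the lists were pooled for being lower, and 23 of 100 regroupings called as many lists. Fewer cells of every kind besides adipocytes could lower the matrix list, but it moved apart from the endothelial markers (exact p = 0.0433 over the 28 pairs of marker lists without muscle). Macrophage and endothelial markers were not told apart in that test (p = 0.281), their own exact p being 0.0866 and 0.0563. Tissue carried in with muscle, which was higher in WT, could raise the lists there, but the difference did not shrink with the muscle covariate (-0.399, 95% interval -0.71 to -0.09). That interval is no test of the difference itself, since the lists were pooled for being lower. The muscle list correlated over the arrays with the macrophage list at r = 0.02, the matrix list at 0.20 and the interferon list at 0.48. The covariate thus had little room to move the macrophage and matrix lists. The number range as a block (-0.3914) tests nothing, since each range holds 3 arrays of each group and the block cannot move the difference. Fewer macrophages and fibroblasts, or lower expression within them, remain open: 17 of 21 macrophage, 21 of 23 matrix and 15 of 20 interferon genes were detected on all 12 arrays, 0, 1 and 0 of the listed genes stand in another list, and counting cells in sections would tell.

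For the stress-responsive genes, the list below and its test were chosen after the gene table had been seen. Sgk1 (0.88, adjusted p = 0.0627), Cdkn1a (1.08, adjusted p = 0.0771), Per2 (1.05, adjusted p = 0.138) and Sdc4 (0.93, adjusted p = 0.113) stood among the largest positive differences. So did the lipid transporter gene Mfsd2a (2.56 ± 0.75, adjusted p = 0.127). None of them passed without a block, and Sgk1 passed with the number range as a block (adjusted p = 0.0432). Exposure to more glucocorticoid could raise the first 4, but a list of other glucocorticoid-responsive genes (camera p = 0.0059, and p = 0.170 with an estimated correlation) decides nothing, since its members could be picked with their values in view. Of its 18 measured genes 13 were higher, from Per1 (0.76), Tsc22d3 (0.64) and Errfi1 (0.60) to Fkbp5 (0.24 ± 0.47), and Angptl4 (-0.18) and Pdk4 (-0.08) were among the 5 that were lower. This stays open, as does a difference in the hour of collection, which might move Per1, Per2 and Dbp (-1.24), and plasma corticosterone with recorded times of death would separate them.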
